A study of Mus musculus with 38 samples.

How the data were processed

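RNA was measured in 14 libraries of mouse CD4 T helper cells in 13 groups, of which 12 held 1 library and 1, WT Th1, held 2. Per the labels' protocols, total RNA was prepared with the mirVana kit, libraries were made with a TruSeq kit, and single reads were sequenced on an Illumina HiSeq instrument. Per the submitters' processing notes, the tools named for the series are TopHat, Cufflinks and SICER and the genome build is mm9; their versions and the gene annotation are not given in the sources used here. The deposited gene tables hold FPKM values, fragments scaled to transcript length and to the mapped fragments of the library, which the authors computed with Cufflinks, per the file headers. The test design, written beforehand, called the unit RPKM; for single reads RPKM and FPKM are the same quantity, and the tests were run as written. The ChIP samples of the series are not analysed here.

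Each table had 23700 entries. In each, 241 symbols were listed at several loci (713 entries), so that such a symbol could not be tied to 1 locus. These entries were not named and not used in the gene lists. They stayed in the tests, the 2-fold counts and the STAT-dependent genes wherever they passed the filters. Cufflinks marked the estimate of 118 genes as failed in at least 1 library; these genes were left out, of which 112 would otherwise have passed the filter. Another 285 entries were marked as low data in every library. The tables give no read counts. The interval that Cufflinks lists around each value narrows with the number of fragments behind it, and from its width each library was estimated to hold 21890000 (STAT6 KO Th2 GATA3 vector) to 38520000 (WT Th1 replicate 2) fragments in genes. Of the estimates below 30 fragments, 64.4% to 75.2% per library lay within 0.02 of a whole number, so these are estimates of depth and no count test was run. The median distance from the value to the upper bound was 12.2% to 16.8% of the value for genes at 1 to 3 FPKM, 4.12% to 5.32% at 10 to 30 FPKM and 1.63% to 2.27% at 100 FPKM or more. These intervals cover counting error only. The exact binomial (Clopper-Pearson) 95% intervals given for shares of genes treat genes as independent draws, which they are not. They cover no variation between libraries or cultures.

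Tests used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) on log2(FPKM + 1), over the 11121 genes with at least 1 FPKM in at least 2 libraries. A change on this scale understates that of low genes. All 14 libraries entered 1 fit with additive terms for lineage, vector culture, STAT4 KO, STAT6 KO, T-bet KO, T-bet vector and GATA3 vector, and a second fit added the interactions of each knockout with its vector. All libraries shared 1 estimate of the spread, which in the planned fit comes from the WT Th1 libraries and from departures from additivity. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Errors beside log2 changes are the standard errors of this fit. Because WT Th1 replicate 2 and the T-bet KO library stood apart from the other 12, a fit with a batch term for these libraries was added after the data were seen, and its values are given beside those of the planned fit. In that fit the batch and T-bet KO terms take up WT Th1 replicate 2 and T-bet KO entirely, so the WT Th1 replicates add nothing to the spread, which comes from departures from additivity in the other 12 libraries (5 residual degrees of freedom against 6). Its T-bet KO estimate compares 1 library with 1. The model was tested on simulated data for each comparison, over 11121 genes with 100 changed by 1 and 100 changed by 2 on the log2 scale. These data were drawn, with independent normal noise, from a fit with the batch term and the interactions. Outside the interaction tests the interactions were set to 0. The simulation thus favours the fit with the batch term, and its counts may overstate what either fit finds in the real data. Without the batch term the model called 13 and 67 of the changed genes for lineage, 32 and 83 for STAT4 KO, 3 and 27 for T-bet KO, 25 and 77 for STAT6 KO, 10 and 62 for the T-bet vector and 9 and 67 for the GATA3 vector. With it, the numbers were 47 and 85, 56 and 91, 28 and 72, 66 and 90, 47 and 90, and 60 and 85. At most 2 unchanged genes were called without the term and at most 12 with it. For the interactions, 0 and 0 changed genes were called without the term, so that a count of 0 says little there; with it, 2 and 24 were called for STAT4 KO with T-bet and 0 and 0 for STAT6 KO with GATA3.

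The gene lists were fixed before the data were examined, as were the groups, the tests, the rule for named genes and the other settings to be tried, apart from those said to have been added later. Of 21 lists, 15 were tested in each comparison with limma's camera at its preset correlation, adjusted over the lists, and again with an estimated correlation: Th1 effector, Th2 effector, interferon (IFN) response, Th17, Treg, Tfh, naive and memory, cytotoxic granule, T cell receptor (TCR) early response, STAT feedback, cell cycle, glycolysis, cholesterol synthesis, CD4 T identity and housekeeping. The preset correlation gave 30 list calls over the 6 comparisons and the estimated correlation gave 0. Median, mean and test had the same sign in every called list. They differed in sign for the IFN response, Treg, Tfh, naive and memory and CD4 T identity lists in T-bet KO, naive and memory in STAT4 KO, cytotoxic granule and STAT feedback in STAT6 KO, and Th1 effector with the GATA3 vector, none of which was called. Tfh was called in no comparison (smallest adjusted p = 0.242, GATA3 vector), nor was CD4 T identity (0.101, STAT4 KO) or housekeeping (0.118, T-bet vector); with the batch term, however, the housekeeping list, a control, was called higher with the T-bet vector (adjusted p = 0.0378, and adjusted p = 0.448 with an estimated correlation). Th17 was called for both vectors only. The lists of CD8 T cell, NK cell, B cell, myeloid, mast cell and basophil, and erythroid markers were summed per library.

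Genes were named by a rule: the 4 manipulated genes; per comparison up to 8 called genes with the largest rise and 8 with the largest fall, at a mean of at least 3 FPKM and with the same sign in every matched pair of libraries; up to 4 members of each list with the largest change; and Ifng, Il4, Il5, Il13, Il12rb2, Il18r1, Il4ra, Cxcr3 and Ccl5. The matched pairs numbered 3 for lineage, 4 for STAT4 KO, 2 for T-bet KO, 3 for STAT6 KO and 2 for each vector, so a gene given as among the largest rises or falls went that way in all of them. For pairs of single libraries, the 5 largest rises and falls at 10 FPKM or more were open to naming. Predicted genes and ribosomal protein, histone and receptor segment genes were not named. Some other genes open to naming by the rule are not reported here. Leaving small RNA genes unnamed was decided after the data were seen, except where 1 was the sole call.

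Comparisons of single libraries give no p-value. A gene with at least 3 FPKM in either library was counted where its log2(FPKM + 1) differed at least 2-fold, over 19 library pairs. For the rescue question, STAT4-dependent genes were those with at least 3 FPKM in both no-vector WT Th1 libraries and at least 2-fold lower in the no-vector STAT4 KO library than in both; STAT6-dependent genes were chosen likewise in the no-vector Th2 pair. They were measured in vector cultures, which had no part in choosing them. Lineage-biased genes (at least 4-fold between no-vector WT libraries, at least 3 FPKM in the higher) were measured in the control-vector pairs. Medians of such lists are given with their percentile among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Near-identical copies of genes were found by aligning annotated pseudogene transcripts to protein-coding transcripts with minimap2 2.31 (at least 95% identity over at least 200 bases), with sequences taken from a mouse genome of the same build with pysam 0.24.0. Plots were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15. The alternatives covered the pseudocount, the filter on low values, scaling, the model terms, the estimate of spread, failed estimates, small RNA genes and leaving out each library in turn.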

Results

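The transcriptomes of CD4 T helper cells were compared between the interferon-producing Th1 lineage and the interleukin-4-producing Th2 lineage, with and without the transcription factors that act in each. STAT4 transmits the IL-12 signal in Th1 cells and STAT6 the IL-4 signal in Th2 cells; T-bet (gene Tbx21) and GATA3 are the lineage-defining factors of Th1 and Th2 cells. The series addresses how the STAT proteins and these factors shape active enhancers and expression, and whether ectopic T-bet or GATA3 restores what is lost without the STAT protein. Naive cells of C57BL/6J mice were sorted and polarised in vitro. Libraries without a vector came from day 7 cultures restimulated for 2 h: WT Th1 (2 libraries), STAT4 KO Th1, T-bet KO Th1, WT Th2 and STAT6 KO Th2 (1 each). Libraries with a retrovirus, labelled day 5, were WT and STAT4 KO Th1 cells with a control or T-bet vector and WT and STAT6 KO Th2 cells with a control or GATA3 vector (1 each). Another label gives 7 days for the Th1 vector cultures, and restimulation of the Th2 vector cultures is not given in the sources used here. Thus 12 of the 13 groups had no replicate. The labels do not say that libraries came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. Libraries had 9793 to 10374 genes at 1 FPKM or more.

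Tbx21, the gene of T-bet (mm9 chromosome 11, 96959321 to 96976645), was listed at 4.18 FPKM in the T-bet KO library, against 88.4 and 152.9 in the WT Th1 libraries. It stood at 245 FPKM in WT and 137 in STAT4 KO cells with the T-bet vector, against 61.0 and 35.1 with the control vector. Gata3 (chromosome 2, 9778705 to 9800227) stood at 589 FPKM in WT and 377 in STAT6 KO cells with the GATA3 vector, against 95.7 and 29.7 with the control vector. Stat4 (chromosome 1, 52065088 to 52164028) was lower in each STAT4 KO library than in its WT counterpart of the same batch: 17.6 against 60.8 FPKM without a vector, 7.57 against 41.0 with the control vector and 6.71 against 37.1 with the T-bet vector. WT Th1 replicate 2, however, had 15.1 FPKM of Stat4, below the no-vector STAT4 KO library, and the fitted change in STAT4 KO was not called (log2 −1.60, adjusted p = 0.222; −2.11 and 0.0246 with the batch term). Stat6 (chromosome 10, 127080042 to 127098043) was 34.6 FPKM in the no-vector STAT6 KO library and 35.6 in WT Th2, 36.1 against 65.9 with the control vector and 23.3 against 48.0 with the GATA3 vector (log2 −0.63, adjusted p = 0.235). Which part of Stat4 or Stat6 the knockouts lack is not given in the sources used here, and a transcript without it still counts towards FPKM, so the Stat6 level does not check the STAT6 KO labels.

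**Figure D1:**
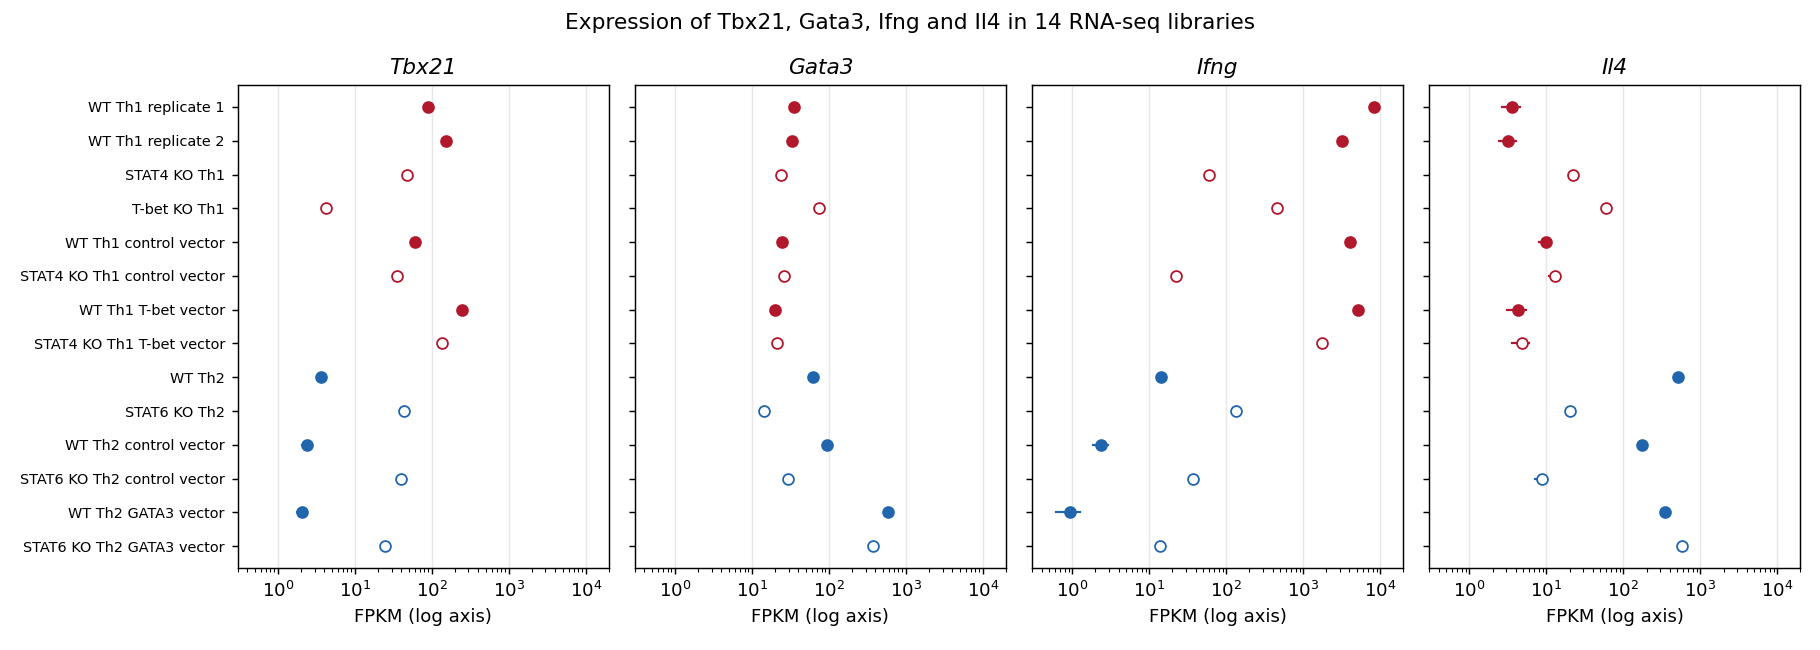
FPKM of Tbx21, Gata3, Ifng and Il4 in each of the 14 libraries on a log axis, with Cufflinks' 95% intervals as lines; filled points are WT, open points knockouts, red Th1 and blue Th2. Tbx21 is lowest among Th1 libraries in the T-bet KO library at 4.18 FPKM, and Gata3 is highest with the GATA3 vector at 377 and 589 FPKM.

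Across the tested genes, WT Th1 replicate 2 resembled the T-bet KO library (Pearson r = 0.976 over genes, which are not independent replicates) more than WT Th1 replicate 1 (r = 0.801). Either of these libraries correlated with the other 12 at 0.676 to 0.801, and the other 12 among themselves at 0.856 to 0.99. Small RNA genes held 20.7% of all FPKM in WT Th1 replicate 2 and 22.2% in T-bet KO, against 4.43% to 7.65% elsewhere, and Cufflinks failed on 49 and 55 genes against 4 to 10. At 2-fold, 2710 genes differed between the WT Th1 replicates (1464 higher and 1246 lower in replicate 2), including Tgtp1, Cxcl10 and Ifit1, interferon-inducible genes that were lower in replicate 2; reads of Tgtp1 are shared with a near-identical copy, so its level is uncertain. The labels name no batch, but these libraries are called a batch from here on.

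**Figure D2:**
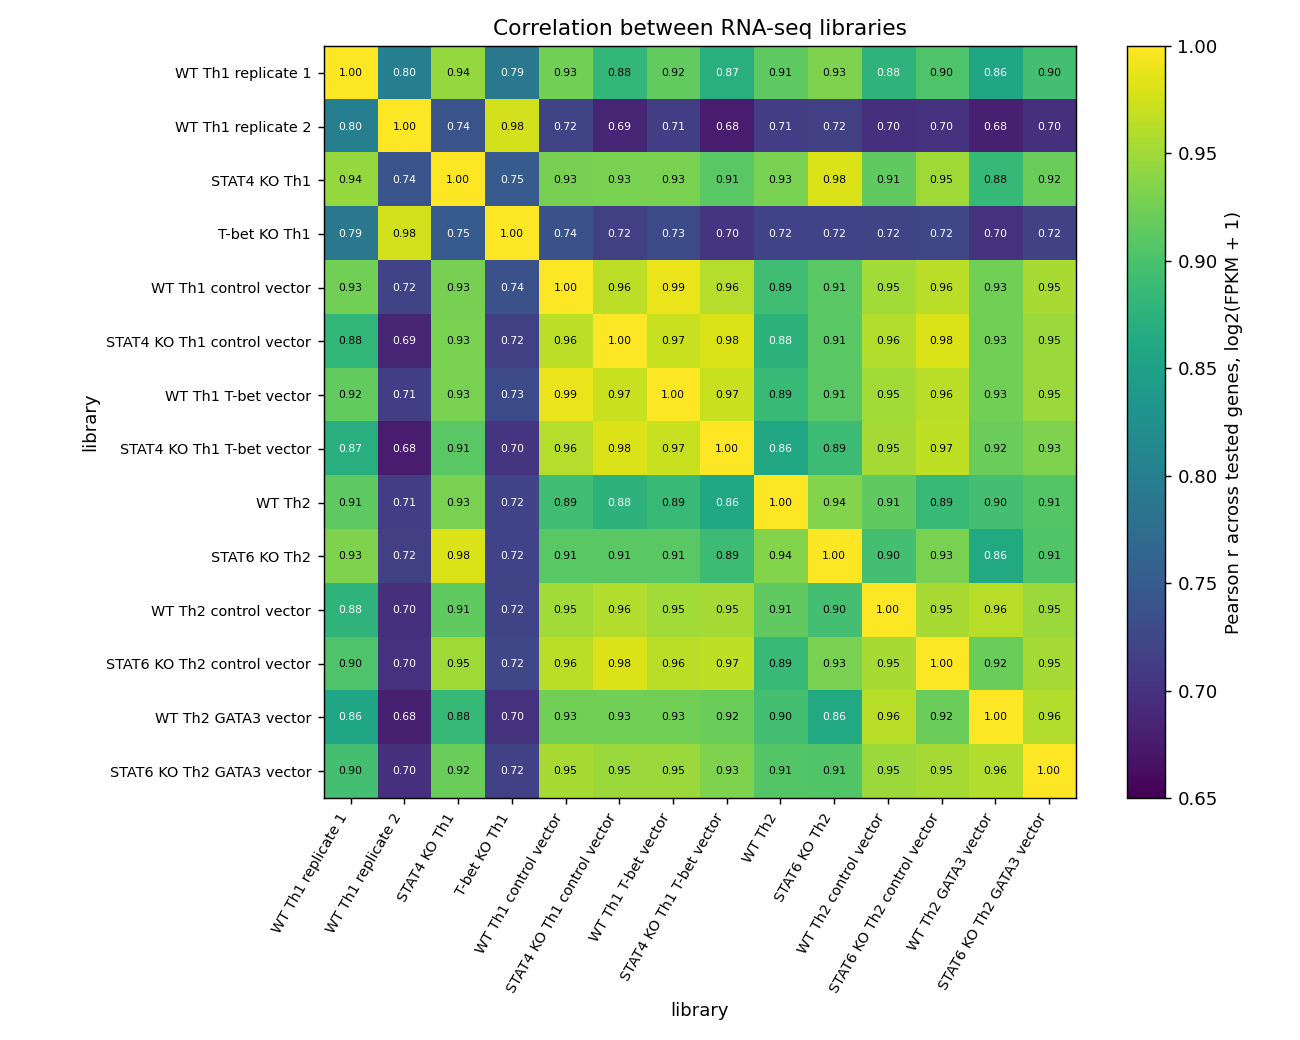
Pearson r of log2(FPKM + 1) across the 11121 tested genes for each pair of the 14 libraries. WT Th1 replicate 2 and T-bet KO correlate at 0.976 with each other and at no more than 0.801 with any of the other 12.

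Ifng, the Th1 signature cytokine, was lower in Th2 than in Th1 cells (log2 −8.46 ± 0.99, adjusted p = 0.00497 by limma). Also lower were Il12rb2 (−5.50 ± 0.33, 1.76e-04) and Il18r1 (−4.71 ± 0.29, 1.76e-04), receptor chains for IL-12 and IL-18, Tbx21 (−4.40 ± 0.25, 1.76e-04) and the chemokine genes Xcl1 (−5.23) and Ccl3 (−4.48). Plac8 (−6.45) and Nkg7 (−5.31), a gene of cytotoxic lymphocytes, also fell. Il4 (4.69 ± 1.02, 0.0476) and Il6 (5.04 ± 0.75, 0.0112) were higher in Th2 cells, with Calcrl (4.49 ± 0.41, 0.00182), Rnd3 (4.30 ± 0.31, 4.73e-04), Epas1 (4.09 ± 0.42, 0.00283), Htr1b (3.88) and Il31 (3.81). Gata3 itself differed by 1.11 (adjusted p = 0.128), Il5 by 2.16 (0.241), Il13 by 0.87 (0.63) and Il4ra by 0.22, none of them called. In all 357 genes were called, 94 higher and 263 lower in Th2 (125 and 207 after quantile normalization). With the batch term 760 were called, 322 of them in both fits and all 322 with the same sign. Il4 (adjusted p = 0.0829), Htr1b (0.0581), Il31 (0.0807), Tube1 (0.0522) and Cxcr3 (0.0785) were then not called. The count was 111 without WT Th2, 145 without WT Th2 control vector, 180 without WT Th1 control vector, 202 without WT Th1 replicate 1 and 742 without WT Th1 replicate 2.

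Of 26 measured Th1 effector genes, 15 fell in Th2, none rose and 11 were not called (18 lower when adjusted over the list alone). The list test gave an adjusted p = 4.49e-14, and adjusted p = 0.231 with an estimated correlation. Of 24 Th2 effector genes, 4 rose, 1 fell and 19 were not called (11 higher and 1 lower adjusted over the list alone). Il4, Il31 and Epas1 were among those that rose, and the list had an adjusted p = 2.35e-06, and adjusted p = 0.498 with an estimated correlation. The IFN response list was lower in Th2 cells, with 4 of 28 genes called, among them Gbp2 (−4.37), Gbp3 (−3.32) and Gbp5 (−2.99), whose reads may be shared within the Gbp cluster. Adjusted over the list alone 7 were lower, and the list had an adjusted p = 0.00526, and adjusted p = 0.666 with an estimated correlation. The STAT feedback list, genes induced by cytokine signalling, was also lower, with Pim2 (−1.71) and Pim1 (−1.05) called among 12 (3 adjusted over the list alone). Its test gave an adjusted p = 0.0153, and adjusted p = 0.331 with an estimated correlation. The TCR early response list (1 of 20 called, Fosb at −1.35; 1 adjusted over the list alone) had an adjusted p = 0.00582, adjusted p = 0.498 with an estimated correlation and 0.0593 with the batch term. Restimulation is labelled for the Th1 but not the Th2 control-vector library. In that pair unequal restimulation cannot be told apart from lineage, for this list or any other gene. The cell cycle list was higher with none of 20 genes called (0 adjusted over the list alone; adjusted p = 0.048, adjusted p = 0.679 with an estimated correlation and 0.904 with the batch term). Cholesterol synthesis was higher with none of 15 called (0 adjusted over the list alone; adjusted p = 0.048, and adjusted p = 0.666 with an estimated correlation).

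STAT4 KO Th1 cells had less RNA of several Th1 cytokine and receptor genes. Ifng fell by 5.21 on the log2 scale (SE 0.90, adjusted p = 0.0439). Il12rb2 (−3.74 ± 0.30, 0.00421) and Il18r1 (−1.71 ± 0.26, 0.0297) also fell. The largest fall was that of Plac8 (−5.73 ± 0.35, 8.3e-04), and other large falls were those of Tmem159 (−3.45), Dgat1, a triglyceride synthesis enzyme (−3.22), Ly6c2 (−3.09; reads may be shared with Ly6c1) and Adam8 (−2.86). Cd160, a receptor of activated lymphocytes, rose most (2.94 ± 0.33, 0.0114), then Pdlim4 (2.74 ± 0.41, 0.0297), Ppic (1.76), Phldb1 (1.44) and Hivep3 (1.43). Tbx21 was not called (−1.01, adjusted p = 0.1; −0.83 and 0.0266 with the batch term), nor were Nkg7 (−2.78, 0.107), Ccl5 (−1.97, 0.105), Il10 (−3.49, 0.0835) and Cxcr3 (−0.54). In total 81 genes were called, 15 higher and 66 lower, and 388 with the batch term (161 higher and 227 lower), with 80 in both fits. With the term Ifng was at −5.37 with an adjusted p = 0.0512. The count was 2 without the STAT4 KO control vector library, 3 without no-vector STAT4 KO, 10 without WT Th1 control vector, 21 without either T-bet vector library, 23 without WT Th1 replicate 1 and 393 without WT Th1 replicate 2.

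The Th1 effector list fell in STAT4 KO cells, with 6 of 26 genes lower, none higher and 20 not called (18 lower adjusted over the list alone). Its median was −1.62, with an adjusted p = 1.03e-11, or adjusted p = 0.169 with an estimated correlation. The STAT feedback list fell, with Pim2 (−1.46 ± 0.22, 0.0297) the 1 call among 12 and Socs3 at −2.21 with an adjusted p = 0.0971 (5 lower adjusted over the list alone). The list had an adjusted p = 2.18e-04, and adjusted p = 0.15 with an estimated correlation. All 15 glycolysis genes had negative estimates, with a median of −0.83, and none was called (3 adjusted over the list alone). Their test gave an adjusted p = 6.27e-06, and adjusted p = 0.475 with an estimated correlation. With the batch term the glycolysis median was smaller, at −0.46, with 1 lower adjusted over the list alone. The camera test then gave an adjusted p = 2.86e-04, and adjusted p = 0.622 with an estimated correlation. The glucose transporter genes Slc2a3 and Slc2a1 were at −1.60 and −1.18. Cholesterol synthesis was lower with none of 15 called (0 adjusted over the list alone; adjusted p = 0.0461, adjusted p = 0.774 with an estimated correlation and 0.101 with the batch term). The Th2 effector list (adjusted p = 0.101), Treg (0.0698) and the IFN response (0.455) were not called, and Il7r, of the uncalled naive and memory list, fell by 1.58 (SE 0.22, adjusted p = 0.0251).

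In T-bet KO Th1 cells 2 genes passed the test: Tbx21 fell by 4.33 (SE 0.35, adjusted p = 0.0087) and Tns4, a gene of a focal adhesion protein, rose by 2.88 (SE 0.31, adjusted p = 0.0419). Tns4 was at 15.7 FPKM against 1.45 and 1.80 in the WT replicates. T-bet KO is 1 library, assumed in the fit to vary like the others, so neither call is a replicated result. The planned fit sets it against WT Th1 libraries of both batches, so its estimates hold part of the batch difference. Genes with large differences that were not called were Ifng, at 454.5 FPKM against 8326 and 3212 (log2 −3.28, adjusted p = 0.337), and Xcl1, at 7.30 against 414.1 and 163.5 (−4.12, 0.317). The same held for Nkg7, at 9.50 against 306.4 and 178.9 (−4.08, 0.315), and Il4, at 60.4 against 3.61 and 3.22 (3.07, 0.337). Il13 was at 78.5 FPKM against 14.7 and 6.21, Gata3 at 74.9 against 35.4 and 32.7 and Il10 at 8.73 against 72.0 and 97.4. With the batch term the T-bet KO estimate is the difference of that library from WT Th1 replicate 2 alone (Tbx21 at −4.89, Tns4 at 2.57), and its spread comes from other groups, so the 98 genes then past the threshold, 62 of them small RNA genes, are no replicated result. The single calls in each direction became 0 higher and 1 lower after upper-quartile scaling or quantile normalization. Without WT Th1 replicate 1 the count was 1; without WT Th1 replicate 2 it was 5421, but T-bet KO is then the sole library of its batch, and T-bet loss and batch cannot be told apart.

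The Th1 effector list in T-bet KO had 1 of 26 genes lower (Tbx21, the knocked-out gene) and 25 not called, with 2 higher and 8 lower adjusted over the list alone. The list test was not passed (adjusted p = 0.179, and adjusted p = 0.384 for the Th1 effector list without Tbx21 and Stat4). The cell cycle list was lower and not called (median −0.55, 14 of 20 estimates negative, adjusted p = 0.431), but against WT Th1 replicate 2 alone its median was 0.63, a difference between single libraries. Across genes, the difference between STAT4 KO and WT with the control vector correlated weakly with that between T-bet KO and the mean of the WT Th1 replicates (Pearson r = 0.162, covariance 0.0623), with no library shared between them. Within the batch, with WT Th1 replicate 2 alone as the T-bet KO control, r was 0.232; with replicate 1 alone it was 0.104.

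STAT6 KO Th2 cells had less RNA of several Th2 genes and more of several Th1 genes. Tbx21 rose by 3.31 (SE 0.24, adjusted p = 8.68e-04) and Il18r1 by 2.96 (0.28, 0.00378), together with Irf8, an interferon-regulated transcription factor (3.12 ± 0.47, 0.0211), Amica1 (2.92) and Igfbp7 (3.62 ± 0.45, 0.011). Il10 (−5.87 ± 0.80, 0.0141), Il24 (−5.77 ± 1.04, 0.0472) and Il6 (−5.08 ± 0.72, 0.0156), cytokine genes, fell. So did Tnfrsf8, the gene of CD30 (−4.52), Rnd3 (−4.24 ± 0.30, 6.74e-04), Epas1 (−4.20 ± 0.40, 0.00383), F2rl2 (−3.99), Tanc2 (−3.87) and Entpd1, an ectonucleotidase (−2.98). Gata3 (−1.45, adjusted p = 0.0912), Il4 (−2.68, 0.328), Il5 (−1.40), Il13 (0.32), Ifng (3.20, 0.191), Xcl1 (3.90, 0.0683) and Il12rb2 (1.27) were not called. The fit called 107 genes, 48 higher and 59 lower (46 and 86 after quantile normalization), and 301 with the batch term (185 higher and 116 lower), with 104 in both. Il24 was not called with the term (0.0607). Without STAT6 KO control vector the count was 15, without no-vector STAT6 KO 16 and without WT Th2 control vector 42.

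Of 24 Th2 effector genes, 3 fell in STAT6 KO (Il10, Il24 and Epas1), 1 rose (Igfbp7) and 20 were not called, with 15 lower and 1 higher adjusted over the list alone. Their median was −2.06 (adjusted p = 5.16e-14, and adjusted p = 0.336 with an estimated correlation). The IFN response list rose, with 5 of 28 genes higher and none lower (13 higher adjusted over the list alone; median 1.13, adjusted p = 5.48e-09, and adjusted p = 0.429 with an estimated correlation). Its calls included Gbp2 (3.49), Gbp5 (3.03) and Gbp3 (2.90), with reads that may be shared within the cluster, while Iigp1 (3.99, adjusted p = 0.0538) and Cxcl10 (3.70, 0.11) were called with the batch term only (0.0349 and 0.0084). The Th1 effector list rose, with 3 of 26 higher (13 higher and 2 lower adjusted over the list alone; adjusted p = 5.58e-07, and adjusted p = 0.336 with an estimated correlation). Naive and memory genes rose as a list with none of 16 called (6 higher and 1 lower adjusted over the list alone; adjusted p = 9.09e-04, and adjusted p = 0.406 with an estimated correlation). All 15 cholesterol synthesis genes had negative estimates (median −0.76), none called, with Lss at −1.43 and Sqle at −0.96 (4 lower adjusted over the list alone; adjusted p = 1.55e-08, and adjusted p = 0.336 with an estimated correlation). All 15 glycolysis genes were also negative, none called (0 adjusted over the list alone; adjusted p = 6.77e-05, and adjusted p = 0.461 with an estimated correlation).

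Genes biased to 1 lineage in no-vector WT cells were followed in the control-vector knockouts, where each value rests on 1 library pair. Of 114 Th1-biased genes, 54 were at least 2-fold lower in STAT4 KO than in WT Th1 (47.4%, exact binomial interval 37.9% to 56.9%) and 3 higher, with a median of −0.94 at percentile 0 of the matched random lists (95% of them between −0.14 and 0.02). In STAT6 KO Th2 cells 48 of them were 2-fold higher than in WT Th2 (42.1%) and 1 lower, with a median of 0.66 at percentile 100 of the random lists. Of 101 Th2-biased genes, 62 were 2-fold lower in STAT6 KO (61.4%, 51.2% to 70.9%) and 2 higher, with a median of −1.38. In STAT4 KO Th1 cells 10 of these 101 were lower (9.9%, 4.85% to 17.5%) and 9 higher, with a median of −0.03 at percentile 46.6 of the random lists.

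The T-bet vector left the fit with no gene called by limma, out of 150 at an unadjusted p under 0.05 (smallest adjusted p = 0.311, for Tbx21 at 1.84 ± 0.28). In STAT4 KO cells Ifng was listed at 1739 FPKM with the T-bet vector against 22.6 with the control vector, Nkg7 at 421.7 against 8.41, Ccl3 at 1559 against 59.7 and Xcl1 at 3531 against 280.6. In WT cells the same pairs were 5199 against 4074 for Ifng, 435.5 against 157.9 for Nkg7, 1245 against 459.8 for Ccl3 and 1125 against 317.2 for Xcl1. The granzyme gene Gzma was at 97.4 against 2.09 FPKM in WT and 5.20 against 1.05 in STAT4 KO cells; reads of granzyme genes may be shared within the family. The 2-fold differences of the vector numbered 60 in WT (37 higher and 23 lower) and 155 in STAT4 KO cells (58 higher and 97 lower), with no replicate check. With the batch term 2 genes were called, 1 of them Tbx21 (1.91, adjusted p = 0.035). The count was 1 without WT Th1 control vector or without STAT4 KO T-bet vector and 3 without WT Th1 T-bet vector.

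None of the members of the lists below was called with the T-bet vector. The Th1 effector list, which holds Tbx21, the gene the vector carries, was higher (3 of 26 higher adjusted over the list alone; adjusted p = 1.04e-09, and adjusted p = 0.103 with an estimated correlation). Without Tbx21 and Stat4 the Th1 effector list had an adjusted p = 1.17e-07. The cytotoxic granule list was also higher (1 of 11 adjusted over the list alone; adjusted p = 3.06e-06, and adjusted p = 0.0719 with an estimated correlation). Naive and memory genes were lower, with 14 of 16 estimates negative and Il7r at −1.19 and Il6ra at −1.04 (2 lower adjusted over the list alone; adjusted p = 2.19e-10, and adjusted p = 0.0713 with an estimated correlation). STAT feedback (adjusted p = 1.27e-04) and Treg genes (0.00171), all 13 of the latter with negative estimates, were lower with 0 calls adjusted over the list alone, and each had adjusted p = 0.0713 with an estimated correlation. Weaker list calls were cholesterol synthesis, lower (adjusted p = 0.0199, and adjusted p = 0.504 with an estimated correlation), and cell cycle, higher (0.0305, and adjusted p = 0.592 with an estimated correlation). So were Th17, lower (0.033, and adjusted p = 0.487 with an estimated correlation), and TCR early response, lower (0.0471, and adjusted p = 0.504 with an estimated correlation). All 4 had 0 calls adjusted over the list alone, and none was called with the batch term (0.0699, 0.222, 0.139 and 0.139). The TCR early response list turned to the opposite direction, uncalled, in a fit of Th1 libraries alone (0.699).

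Whether ectopic T-bet returned STAT4-dependent genes to the WT level was measured over 283 genes. With the control vector 145 of them were at least 2-fold lower in STAT4 KO than in WT cells (51.2%, exact binomial interval 45.3% to 57.2%), and with the T-bet vector in the knockout 141 were (49.8%, 43.8% to 55.8%), against WT cells with the control vector in both cases. The medians were −1.03 and −0.99, both at percentile 0 of the matched random lists. Of the 145 genes, 116 stayed 2-fold lower and 29 did not, while 25 others of the 283 became 2-fold lower with the T-bet vector, so that the flow out and in was about equal. Of the 29, 26 came within 2-fold and 3 rose above WT by 2-fold: Nkg7 (−4.08 to 1.41), Ccl3 (−2.92 to 1.76) and Ccl4 (−1.48 to 1.72), named after their values were seen. Ifng went from −7.43 to −1.23 and Il12rb2 from −4.40 to −3.00. Plac8 went from −6.01 to −6.38, Il7r from −1.38 to −3.16, Dgat1 from −2.48 to −2.87 and Tmem159 from −3.49 to −3.44. Chosen without WT Th1 replicate 1, the list held 1756 genes and the shares were 11.2% and 13%. That choice rests on no-vector STAT4 KO against WT Th1 replicate 2, a pair that crosses the batch and differs 2-fold by 3646 genes. The list then takes in batch differences as well as STAT4 dependence. Without replicate 2 it held 419 genes and the shares were 46.5% and 45.1%.

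With the GATA3 vector Il9, a Th2-associated cytokine gene, rose by 7.44 (SE 0.54, adjusted p = 4.51e-04), from 3.28 to 229 FPKM in WT and from 0.162 to 447.5 in STAT6 KO cells. Hdc, the histamine-forming enzyme, rose by 6.88 (SE 0.29, 1.43e-05), and Mcpt8, a basophil protease gene, by 5.63 (0.17, 1.8e-06), from 0.0941 to 59.2 FPKM in WT and from a listed 0 to 42.7 in STAT6 KO cells. Slc7a8, an amino acid transporter gene (4.96), Calca (4.35), Hamp (4.03; its reads may be shared with a copy), Sord (3.97 ± 0.27, 3.3e-04) and Gata3 (3.39 ± 0.38, 0.00473) also rose, and Gpr18 fell (−1.44 ± 0.25, 0.0365). Il5 (4.75, adjusted p = 0.0784), Il4 (2.94, 0.459) and Il13 (2.73, 0.564) were not called. In STAT6 KO cells Il5 was at 207.6 FPKM against 0.0992, Il4 at 569.8 against 8.71 and Il13 at 620.0 against 15.3. In total 117 genes were called, 115 higher and 2 lower, and 322 with the batch term (295 and 27), with 116 in both fits. Without WT Th2 control vector the count was 33, without STAT6 KO control vector 40, without WT Th2 GATA3 vector 52 and without STAT6 KO GATA3 vector 53.

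Of 24 Th2 effector genes, 2 rose with the GATA3 vector, Il9 and Gata3, the gene the vector carries, and 22 were not called (6 higher adjusted over the list alone). The list's median was 1.46 (adjusted p = 1.84e-04, and adjusted p = 0.581 with an estimated correlation), and for the Th2 effector list without Gata3 the adjusted p was 0.00177. All 16 naive and memory genes had negative estimates, none called (0 adjusted over the list alone; adjusted p = 0.00177, and adjusted p = 0.581 with an estimated correlation), with Ccr7 at −1.84. Glycolysis was higher with 14 of 15 estimates positive and none called (0 adjusted over the list alone; adjusted p = 0.0194, and adjusted p = 0.844 with an estimated correlation). The Th17 list was higher with 1 of 11 genes called, Il1r1 (3.18), an interleukin-1 receptor gene (3 adjusted over the list alone; adjusted p = 0.0457, adjusted p = 0.616 with an estimated correlation and 0.198 with the batch term). Summed markers of mast cells and basophils stood at 69.3 FPKM in WT and 46.5 in STAT6 KO cells with the GATA3 vector, against 0.813 and 0.876 with the control vector, and Mcpt8 made up most of each.

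Of 522 STAT6-dependent genes, 184 were at least 2-fold lower in STAT6 KO than in WT cells with the control vector (35.2%, exact binomial interval 31.1% to 39.5%), and 82 were with the GATA3 vector in the knockout (15.7%, 12.7% to 19.1%). The medians were −0.70 and −0.00; both lay at percentile 0 of the matched random lists, of which 95% had medians of −0.06 to 0.00 and of 0.06 to 0.14. Of the 184, 69 stayed 2-fold lower, 94 came within 2-fold and 21 rose above WT by 2-fold, while 13 others of the 522 became 2-fold lower. Il5 (−3.90 to 3.67), Il4 (−4.17 to 1.71) and Asb2 (−3.84 to 1.61) were among the 21, as was Gata3, whose level there includes the vector's transcript. Still lower were Tnfrsf8 (−4.98 to −4.69), Rnd3 (−4.45 to −4.27), Epas1 (−4.22 to −3.95), Tanc2 (−4.31 to −3.93) and Entpd1 (−2.24 to −2.38). Il24 went from −6.68 to −2.60 and Il10 from −5.24 to −2.68. Each of these values rests on 1 pair of libraries.

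**Figure D3:**
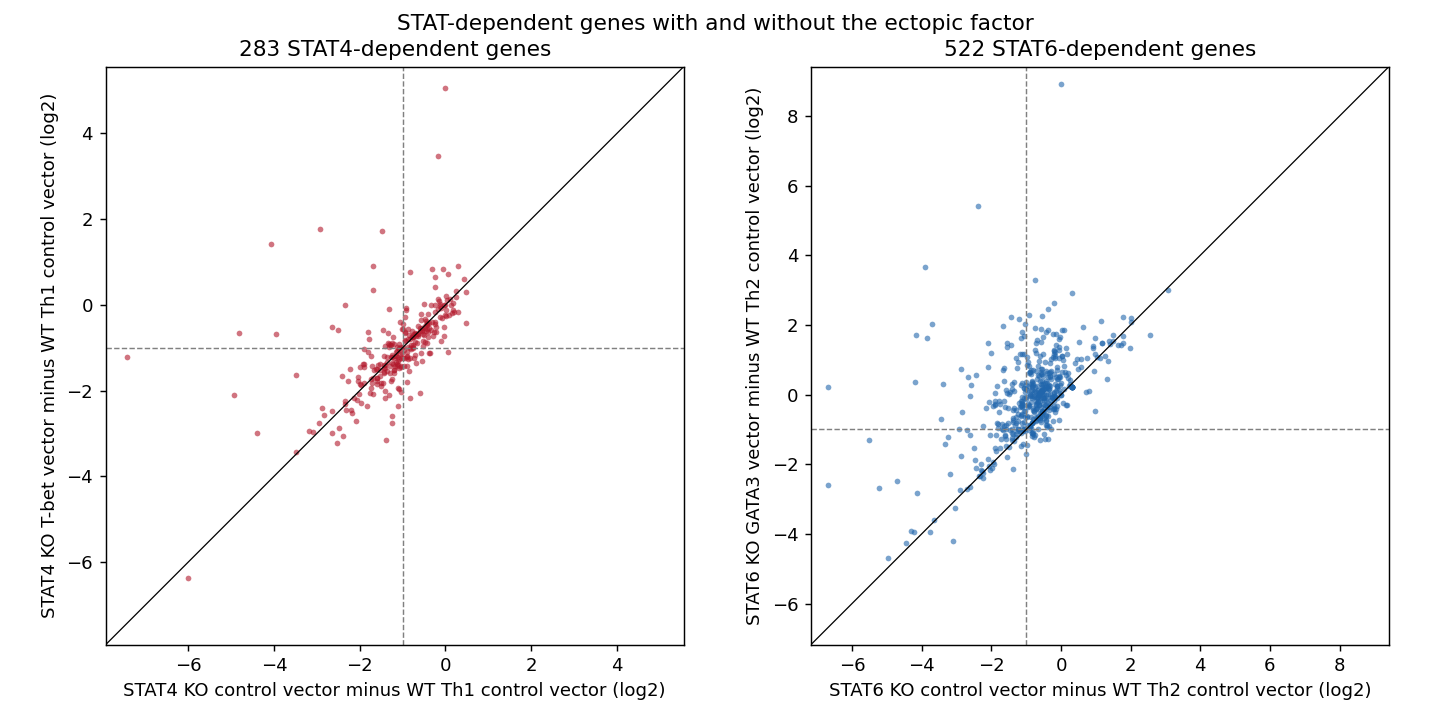
Each point is a STAT4-dependent (283) or STAT6-dependent (522) gene; the log2 difference of the knockout from WT cells with the control vector is on the x axis for the knockout with the control vector and on the y axis for the knockout with the T-bet or GATA3 vector. Dashed lines mark −1 and the diagonal equality; 116 of 145 genes stay below −1 with T-bet and 69 of 184 with GATA3.

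Whether the vectors acted differently in knockout and WT cells was tested as an interaction. For T-bet, limma called 1 gene, the small RNA gene Mir215 (6.19 ± 0.32, adjusted p = 0.00421), with 50 genes at an unadjusted p under 0.05; Nkg7 was at 3.90 (0.539), Ifng at 5.17 (0.999) and Ccl5 at 2.14. The call was lost without the STAT4 KO control vector library (0 genes). For GATA3, limma called 0 genes, with 176 at an unadjusted p under 0.05. The smallest p-values belonged to Tph1 (3.24, adjusted p = 0.329), whose enzyme makes the serotonin precursor, Ctla2b (3.37, 0.385), Htr1b (4.32, 0.385), Il5 (5.20, 0.385) and Spink4 (−2.52, 0.385). With the batch term 2 and 5 genes were called, the latter including Tph1 (0.00481) and Spink4 (0.0362).

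The WT Th1 replicates themselves cross the batch, so their 2710 differences at 2-fold do not measure scatter within a batch. No pair of replicates lies within a batch. The other matched pairs differed by fewer genes than these replicates, except where the pair crossed the batch. The STAT4 KO differences numbered 785 against WT Th1 replicate 1 (366 higher and 419 lower) and 415 with the control vector (94 and 321), and 3646 against replicate 2. T-bet KO differed from WT Th1 replicate 2 by 432 genes (211 and 221) and from replicate 1 by 2966. STAT6 KO differences numbered 905 without a vector (383 and 522), 522 with the control vector (324 and 198) and 506 with the GATA3 vector (339 and 167). WT Th2 differed from WT Th1 by 1450 genes (replicate 1), 4213 (replicate 2) and 610 (control vector). The GATA3 vector pairs differed by 453 genes in WT and 499 in STAT6 KO cells.

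**Figure D4:**
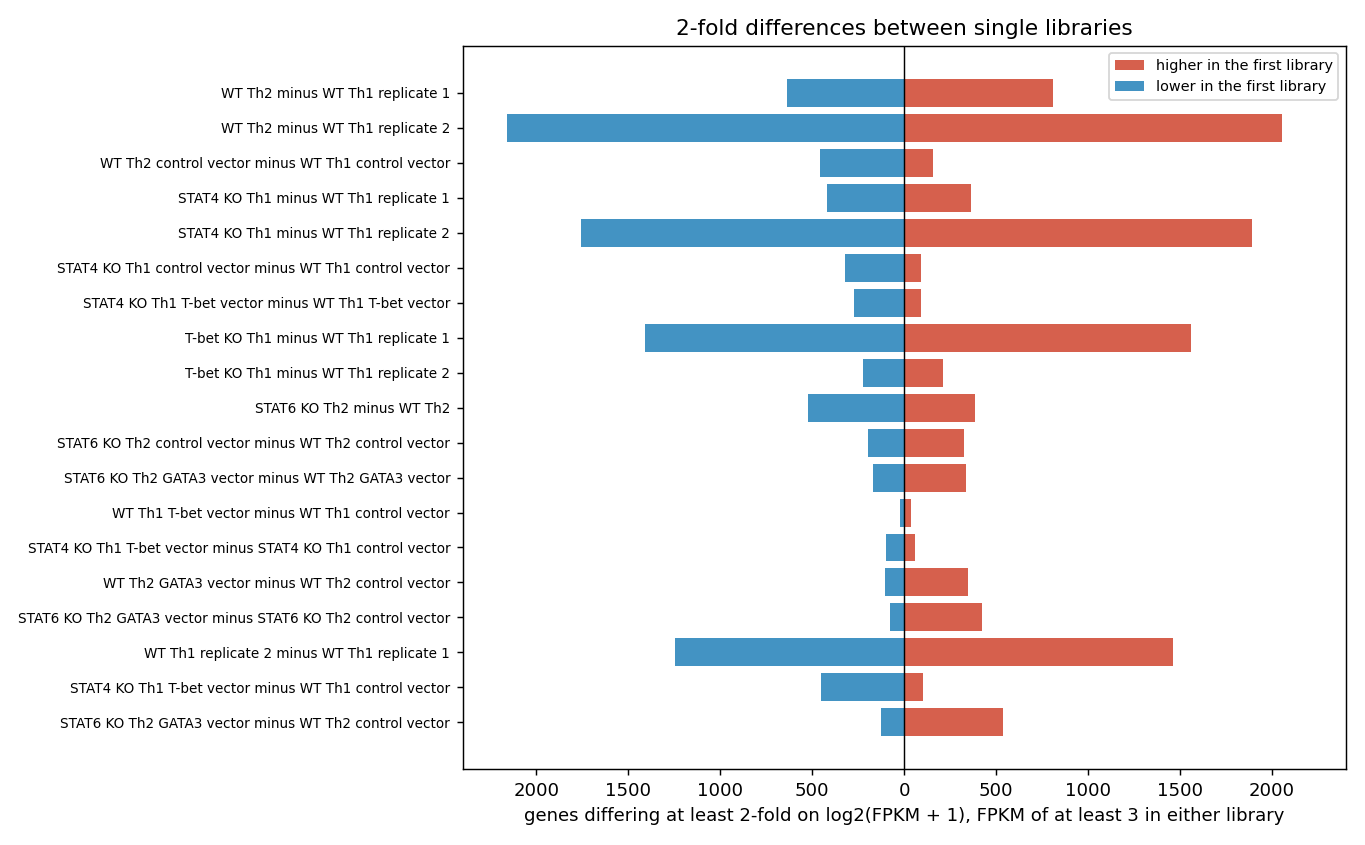
Number of genes at least 2-fold higher (bars to the right) or lower (bars to the left) in the first than in the second library of each pair. The WT Th1 replicates, which themselves cross the batch, differ by 2710 genes, and the other pairs that cross it by 2966 to 4213.

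Markers of other cell types were low beside those of CD4 T cells, whose 12 identity genes summed to 1650 to 3140 FPKM. The sums were 1.84 to 5.65 FPKM for CD8 T cells, 0.0431 to 0.636 for NK cells, 2.59 to 11.3 for myeloid cells and 0.104 to 1.41 for erythroid cells. B cell markers reached 96.2 FPKM in WT Th1 replicate 2, where H2-Ab1 gave 81.9, and 84.1 in T-bet KO, against 3.09 to 37.3 elsewhere. Their sum was lower in each STAT4 KO library than in WT: 4.45 FPKM against 29.7 in replicate 1 and 96.2 in replicate 2, 14.3 against 37.3 with the control vector and 10.6 against 23.1 with the T-bet vector. In STAT6 KO it was 3.09 against 17.7 FPKM without a vector, 13.6 against 23.5 with the control vector and 30.6 against 24 with the GATA3 vector. Cd74 or H2-Ab1 made up the largest part in each library. In STAT4 KO H2-Aa (−1.10, adjusted p = 0.111; −1.25 and 0.044 with the batch term), Cd74 (−1.35, 0.155) and H2-Ab1 (−2.32, 0.277) were not called without the batch term.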

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

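The interaction was tested as planned; setting it beside a test without small RNA genes was chosen after the result was seen. Mir215, a microRNA gene, came up because the T-bet vector's change differed between STAT4 KO and WT cells in the interaction test (6.19 on the log2 scale, SE 0.32, adjusted p = 0.00421 by limma). It was listed at 71.8 FPKM in STAT4 KO Th1 T-bet vector, with a Cufflinks interval of 0 to 215.4, at 12.9 FPKM in T-bet KO (0 to 31.1), and at 0 in the other 12 libraries. The change thus rests on 1 library whose interval reaches 0. With small RNA genes left out, 0 genes were called in this interaction.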

How the results depend on the processing

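The tests with a batch term, without the manipulated genes in the lists, without the batch libraries (WT Th1 replicate 2 and T-bet KO), with failed estimates kept, without small RNA genes and with a single WT Th1 replicate as T-bet KO control were chosen after the results were seen; the splits of all libraries and all others were planned, and those within the other batch were not. Many of the 84 calls of named genes were chosen for a large change with the same sign in every matched pair of these libraries. A reversal was therefore unlikely from the start. Under 12 changes of setting, none of the 84 calls changed direction where it could be compared. Of them 77 were called with the batch term, 75 of 82 without the batch libraries, 76 at a pseudocount of 0.1, 53 without the filter, 65 of 77 at 5 FPKM, 79 after upper-quartile scaling, 78 after quantile normalization, 84 without the trend, 64 with a lineage by vector term, 83 with failed estimates kept, 83 of 83 without small RNA genes and 1 of 53 in a fit per lineage. That fit has fewer libraries to estimate the spread from. Over all settings and left-out libraries, 1065 comparisons of named genes stayed called and 358 were not, and for gene lists 83 comparisons stayed and 44 were weaker, with 1 reversed. Depth limits low genes most: at 1 to 3 FPKM the interval reached a median of 12.2% to 16.8% above the value, against at most 2.27% at 100 FPKM or more.

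For counts of called genes, the cause was not tested unless stated. Planned counts were 357 (Th2 against Th1), 81 (STAT4 KO), 2 (T-bet KO), 107 (STAT6 KO), 0 (T-bet vector), 117 (GATA3 vector), 1 (STAT4 KO by T-bet vector) and 0 (STAT6 KO by GATA3 vector). The batch term gave 760, 388, 98, 301, 2, 322, 2 and 5; the 98 for T-bet KO rest on that library against WT Th1 replicate 2 alone. Without the batch libraries the counts were 757, 346, 309, 2, 316, 2 and 13, with none for T-bet KO, whose library was left out. Without the filter on low values STAT4 KO gave 21, T-bet KO 56, the T-bet vector 1, the GATA3 vector 321 and the interactions 93 and 531. At 5 FPKM in 2 libraries lineage gave 205, T-bet KO 1, STAT6 KO 59, the GATA3 vector 15 and the T-bet interaction 0. A fit per lineage gave 1 for STAT4 KO and 0 for T-bet KO, STAT6 KO, the GATA3 vector and the T-bet interaction, with 562, 2344, 1720 and 27 genes of the last 4 at an unadjusted p under 0.05. A lineage by vector term gave 27 for STAT4 KO, 1 for T-bet KO and 62 for the GATA3 vector. At a pseudocount of 0.1 T-bet KO gave 1, the GATA3 vector 59 and the T-bet interaction 0. Upper-quartile scaling gave 1 for T-bet KO, and quantile normalization gave 1 for T-bet KO and 1 for the T-bet vector. Without small RNA genes the T-bet interaction gave 0, since its sole call is such a gene. All-gene medians moved by under 0.1 with scaling, most for Th2 against Th1 (−0.04 to 0.05 after quantile normalization).

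Leaving out each library in turn gave 111 to 742 calls for lineage, 2 to 393 for STAT4 KO, 1 to 5421 for T-bet KO, 15 to 96 for STAT6 KO, 0 to 3 for the T-bet vector, 33 to 53 for the GATA3 vector, 0 to 1 for the T-bet interaction and 0 to 0 for the GATA3 interaction. Leaving out T-bet KO gave no value for its comparison, and leaving out a T-bet or GATA3 vector library gave none for its interaction, since the terms could not then be estimated. A fit per lineage gives no lineage comparison. Pairing was considered by replicate number only. No paired analysis was possible because the RNA-seq groups share fewer than 2 replicate numbers, and the ChIP groups are not analysed here. Libraries can also be matched by culture, which entered the planned fit as the terms for vector culture, T-bet vector and GATA3 vector.

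The share of STAT4-dependent genes still 2-fold lower with the T-bet vector (49.8%) was 57.5% at a pseudocount of 0.1, 56.4% at 1.5-fold, 57.1% at 10 FPKM and 40.2% after quantile normalization. The control-vector shares at a pseudocount of 0.1 and at 1.5-fold were 56% and 51.9%, so that there more genes were lower with the T-bet vector than with the control vector, the reverse of the order of 49.8% and 51.2%. Without WT Th1 replicate 1 the list was chosen across the batch. The share with the T-bet vector was then 13%, again above the control vector's 11.2%, and it was 45.1% without replicate 2. With the control vector (51.2%) it was 58.7% at 10 FPKM, 43.9% after quantile normalization, and 11.2% to 46.5% with a WT Th1 replicate left out. For STAT6-dependent genes the share with the GATA3 vector (15.7%) was 20.1% at a pseudocount of 0.1 and 20.7% after quantile normalization, and with the control vector (35.2%) 40.2% at 1.5-fold. The correlation of STAT4 KO and T-bet KO differences (0.162) was 0.128 at a pseudocount of 0.1, 0.172 after quantile normalization, 0.232 with WT Th1 replicate 2 only, 0.104 with replicate 1 only and 0.253 with replicate 2 and no small RNA genes. At a minimum of 10 FPKM, fewer genes enter the 2-fold counts: 396 for WT Th2 against WT Th1 with the control vector, 266 for STAT4 KO with the control vector, 287 for T-bet KO against replicate 2, 326 and 315 for STAT6 KO with the control and GATA3 vectors, 270 and 312 for the GATA3 vector in WT and STAT6 KO, and 383 for STAT6 KO GATA3 vector against WT control vector.

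Without Tbx21, Gata3, Stat4 and Stat6 in the lists, the 30 list calls all held. Of these 30, 0 held with an estimated correlation, where adjusted p was 0.169 for Th1 effector in STAT4 KO, 0.336 for Th2 effector and 0.429 for IFN response in STAT6 KO. Th1 effector in T-bet KO (0.179) was called after quantile normalization (0.00628) and in a fit per lineage (0.0239), and not with an estimated correlation (0.989) or without Tbx21 and Stat4 (0.384). With the batch term its values (0.0181, and 0.143 without Tbx21 and Stat4) compare 1 library with 1 and decide nothing. The fits without the term set T-bet KO against WT Th1 libraries of both batches. Their values for this list thus hold part of the batch difference and decide nothing either. The TCR early response list with the T-bet vector reversed, from lower to higher, in a fit per lineage (0.699). Moving the knockout label among the 7 Th1 libraries other than T-bet KO, 3 of 35 splits gave at least the real 81 genes, so that by this count chance was not excluded. The others were not free of the samples' structure. They gave 461, with no-vector STAT4 KO and both Th1 control-vector libraries as knockouts, a labelling that shares no-vector STAT4 KO and STAT4 KO control vector with the real one, and 5002, with WT Th1 replicate 2 and both T-bet-vector libraries, which singles out the batch library. Without the batch libraries the STAT4 KO count was 346, and among 10 splits, too few for a share under 0.05, the highest other was 300, again with no-vector STAT4 KO and both Th1 control-vector libraries; the remaining 8 gave 0 or 1. For STAT6 KO, 1 of 10 splits gave 107 genes, the real one, and the highest other gave 3; 10 splits are too few for a share under 0.05.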

Other observations

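The tests of explanations, the batch term and the genes described here outside the fixed lists were chosen only after the results were seen; the fit without the term was planned. Cyp11a1, which makes pregnenolone, was at 91.7 FPKM in no-vector WT Th2 and 0.344 in STAT6 KO, and with the GATA3 vector at 108.3 in WT and 330.1 in STAT6 KO, against 6.81 and 0.487 with the control vector. Tph1, which makes the serotonin precursor, was at 2.14 FPKM in WT and 29.3 in STAT6 KO cells with the GATA3 vector and at 0.0691 or less in the other 12 libraries. Il1rl1, the IL-33 receptor gene, was at 150.7 and 39.9 FPKM with the GATA3 vector against 3.16 and 1.46 with the control vector. The growth factor gene Areg was at 302.4 and 716.7 FPKM against 90.2 and 76.3.

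S100a4 and Cd160 were higher in the no-vector libraries of both STAT knockouts than in WT. S100a4 stood at 131.3 FPKM in no-vector STAT4 KO against 5.81 and 4.16 in WT Th1, and at 221.4 in no-vector STAT6 KO against 13.2 in WT Th2. With the control vector it was at 13.3 in STAT4 KO against 22.2 in WT Th1, and at 18.3 in STAT6 KO against 1.85 in WT Th2. Cd160 was at 37.5 FPKM in no-vector STAT4 KO against 6.71 and 1.82 in WT Th1 and at 28.1 in no-vector STAT6 KO against 9 in WT Th2, and with the control vector at 52.9 and 66.1 against 5.58 and 21.0. Foxp3, the regulatory T cell factor, was at 8.38 FPKM in STAT6 KO against 0.155 in WT Th2 with the control vector (2.30 in the fit, adjusted p = 0.108 by limma, and 0.0392 with the batch term); in STAT4 KO it was at 10.46 against 9.32 in WT Th1 with the control vector (0.66, adjusted p = 0.556).

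WT Th1 replicate 2 and the T-bet KO library stood apart from the other 12. Loss of T-bet is argued against as the cause, since replicate 2 had 1.73 times as much Tbx21 as replicate 1 (152.9 against 88.4 FPKM). Different treatment of reads shared with pseudogene copies is argued against as the whole cause, as 24.7% of 10167 genes without such a copy differed 2-fold between the WT Th1 replicates; the share was 29.8% of 634 genes with one, for which it stays open. Of 166 genes of at most 150 nt with a value in either library, 119 (71.7%) were at 0 in all of the other 12, against 0.36% of those of 1000 nt or more, which is consistent with short genes having been lost or set to 0 in the other 12. That is argued against as the whole cause, since 2326 of 9972 genes of 1000 nt or more still differed 2-fold between the WT Th1 replicates (r = 0.893, against 0.976 of replicate 2 with T-bet KO over these genes), and which step of culture, library preparation or processing differed remains open.

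STAT4 KO Th1 and STAT6 KO Th2 libraries were more alike (r = 0.981 without a vector and with the control vector) than WT Th1 replicate 1 and WT Th2 (0.913) or the WT control-vector libraries (0.952). Knockout libraries of a single genotype under both labels would need similar Stat4 levels, but Stat4 was 4.81 and 2.53 times as high in STAT6 KO as in STAT4 KO. Stat4 also varied between WT libraries, from 41.0 FPKM in WT Th1 control vector to 7.75 in WT Th2 GATA3 vector. It was 7.80 FPKM in STAT6 KO Th2 GATA3 vector and 6.71 in STAT4 KO Th1 T-bet vector. Beside WT cells of the same culture and batch, Stat4 was lower in each STAT4 KO library. In STAT6 KO it was 84.47 FPKM against 53.35 without a vector and 19.2 against 21.2 with the control vector. With the GATA3 vector it was 7.80 against 7.75. These values argue against STAT4 KO cells under both labels. Whether STAT6 KO cells lay under both labels stays open, since Stat6 was hardly lower in no-vector STAT6 KO (34.6 against 35.6 FPKM). A hypothesis is that lineage-biased expression is lost without either STAT protein, and the values it needs are there: the median lineage difference, over genes chosen in the other kind of culture, went from 2.38 in WT to −0.10 in the knockouts over 143 genes (ratio −0.0432) and from 1.37 to −0.12 over 231 genes (−0.0896). A batch shared by the knockout libraries could add to this and cannot be told apart, since the spread of genes without lineage bias was 0.571 times as wide between the knockouts as between WT libraries without a vector and 0.912 times with the control vector.

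Mast cell and basophil genes were high in both GATA3 vector libraries, with Mcpt8 at 59.2 and 42.7 FPKM and Cpa3 at 9.64 and 2.34. Mast cells or basophils in the cultures are argued against, as Fcer1a and Ms4a2, which both cell types express abundantly, were listed at 0 in both libraries, and naive cells had been sorted before culture. Cpa3 was also at 10.2 FPKM in no-vector WT Th2 cells. Whether ectopic GATA3 induces these genes in the T cells stays open: the smallest change of Mcpt8, Hdc and Il9 in either genotype was 5.45 on the log2 scale, but they had been chosen for their rise, so this decides nothing.

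A further hypothesis was that the STAT4-dependent genes that came back with the T-bet vector are those that need T-bet. Of the 145 genes lower with the control vector, 29 came back and 116 did not; 25 others became 2-fold lower, so part of this crossing may be scatter. Their median differences between T-bet KO and WT Th1 replicate 2 were −0.87 and −0.30, a difference of −0.57, and 14 of 29 and 21 of 116 were 2-fold lower in T-bet KO. This lay at percentile 0.2 of random divisions of the 145 genes (95% between −0.36 and 0.29), but fell short of the difference of 1 set for the test, and it rests on 1 T-bet KO library, so the question stays open. Among the genes that came back, Nkg7 (−4.10), Cldnd2 (−4.10) and Ctsw (−3.12) were lower in T-bet KO, and Eomes (1.34) and Ccl5 (1.09) higher.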
